A study of Terfezia claveryi
Helianthemum almeriense and Helianthemum almeriense with 9 samples.

How the data were processed

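The series holds RNA sequencing of Helianthemum almeriense roots in 9 libraries, 3 from each of 3 groups, with 1 table per library. Per the labels' protocols, RNA was extracted from frozen roots with a CTAB and phenol method and sequenced as paired Illumina reads, and the series design states that the replicates are biological. Groups were taken from the source names in the labels, and replicate numbers from the descriptions, which differ from the plant numbers in the titles of the mycorrhizal libraries.

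Each deposited table lists the same 19695 contigs in the same order with 1 column of normalised reads. Per the submitters' processing notes, FastQC, Bowtie2 2.3.0, SAMtools 1.7 and DESeq2 were used. The assembler, the annotation and the filter on contigs were not given in the sources used here. The file header does not name a log, so the unit was read from the values: the deposited values are log2 of normalised reads plus 1. After undoing the log, 100% of the values were whole multiples of 1 step per library (within 0.01 reads, largest deviation 0.002 reads), which recovers the reads per contig. The reciprocals of the steps equalled median-of-ratios factors computed on the same contigs to a relative difference of 6.9e-11. No contig held fewer than 45 reads over the 9 libraries, a mean of 5 per library, so low contigs had been removed before deposit. Plant reads per library, summed over the recovered reads, ranged from 7454712 to 29174454. Removed contigs and fungal reads are not part of these totals.

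The design fixed before the data were examined foresaw edgeR on counts, which was not used because the tables hold log2 values. The test was limma 3.58.1 in R 4.3.3 on the deposited log2 values in its place: 1 mean per group over all 9 libraries with no covariate, empirical Bayes moderation with a mean trend and robust estimation, and Benjamini-Hochberg adjustment within each comparison with a threshold of 0.05. The fit had 6 residual degrees of freedom. Contigs with at least 10 recovered reads in at least 3 libraries were tested, 19463 in all, and 232 were left out. A log2 fold change is a difference of mean log2(normalised reads + 1), which understates the change of contigs with few reads. No length correction was applied, so levels of different contigs are not comparable as molar amounts. Contigs of 1 gene, or of near-identical copies, may share reads and were not merged.

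The method was tested on simulated data with 200 changed contigs drawn on the real means and library sizes at a dispersion of 0.1. The changed contigs were taken only from those above a minimum mean level, so the recovery rates do not cover contigs with the fewest reads. For well-watered mycorrhizal against non-mycorrhizal libraries, 7% of 2-fold and 82% of 4-fold changes were recovered with 1 false call among 19574 contigs. For drought-stressed against well-watered mycorrhizal libraries the values were 19% and 93% with 7 false calls among 19567 contigs. At this replication most simulated 2-fold changes were not called. The simulation used the same dispersion for every contig and no shift shared by the contigs of a library. Real libraries deviated unequally from their group mean, with SDs across contigs from 0.2667 to 0.9571 (log2). The simulated rates are therefore not rates of false or missed calls in the real data.

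Named contigs followed a rule fixed before the data were examined. For each of the mycorrhiza and drought effects it takes at most 2 contigs that rose and 2 that fell, with the smallest p among those with an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean of at least 50 reads and no overlap between the libraries of both groups. Gene lists fixed in advance for symbiosis and drought pathways and for other tissues could not be matched, since the contigs carry no names, and no set test was run.

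Shares of reads, contigs read in one group only and the share of the most abundant contigs were computed on the recovered reads, the last compared by exact two-sided permutation tests. Because the mycorrhiza and drought effects share the well-watered mycorrhizal libraries, 100 data sets with no effect were simulated from permuted residuals, and the correlation, covariance and overlap were set beside their simulated values. Comparisons were refitted with each library left out, with other filters, with the replicate number as a block, with the compared groups alone, with thinned reads and with limma-voom. Other pseudocounts, other scalings, moderation without robust estimation, weights per library and the removal of a pair of libraries were added after the data were seen. Simulation of mixtures and tests on library structure used Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3, and figures used matplotlib 3.10.9.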

Results

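Helianthemum almeriense is a Mediterranean shrub whose roots form mycorrhiza with the desert truffle Terfezia claveryi. RNA of secondary and tertiary roots was sequenced from 9 libraries in 3 groups of 3 biological replicates: non-mycorrhizal plants, well-watered mycorrhizal plants and drought-stressed mycorrhizal plants. The non-mycorrhizal plants had grown for 5 months in pots, and the mycorrhizal plants were sampled after inoculation with fungal spores for 3 months. Soil moisture was kept over 75% in the non-mycorrhizal and well-watered groups. In the drought-stressed group it was lowered to 40% until the shoot water potential was below -2 MPa. No group of non-mycorrhizal plants under drought was analysed here, so the drought effect was measured in mycorrhizal roots only.

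Expression was measured on 19695 assembled plant contigs, each known only by an identifier. The sources used here pair no contig with a gene name, a function or a genome position, so contigs are described by their levels and by how they changed over the 3 groups. The non-mycorrhizal libraries held 27477005, 28392201 and 27328371 plant reads for replicates 1 to 3. The well-watered mycorrhizal libraries held 19226195, 12904108 and 7454712, and the drought-stressed ones held 19742476, 29174454 and 16172633. The RNA of mycorrhizal roots also contained fungal reads, which the submitters analysed elsewhere. Contigs without a single read numbered 135, 57 and 109 in the non-mycorrhizal libraries, 60, 326 and 448 in the well-watered mycorrhizal libraries and 385, 498 and 344 in the drought-stressed libraries.

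Drought-stressed libraries lay apart from both other groups on the first principal component of the log2 values, which held 38.22% of the variance. Replicates were not equally close. Among contigs with at least 200 reads in the pair, 1 contig differed at least 4-fold between well-watered mycorrhizal replicates 2 and 3, whereas replicate 1 differed that much from replicate 2 in 908 contigs and from replicate 3 in 884. In the drought-stressed group 11 contigs lay that far apart between replicates 1 and 3, against 1110 between replicates 1 and 2 and 1256 between replicates 2 and 3. In the non-mycorrhizal group the numbers were 51 for replicates 1 and 3, 177 for replicates 2 and 3 and 834 for replicates 1 and 2. Non-mycorrhizal replicate 3 had the middle value of its group in 63.4% of tested contigs, where 33.3% is given by chance. On the second principal component (24.73% of the variance) well-watered mycorrhizal replicate 1, at -20.6, lay between the non-mycorrhizal libraries (-89.49 to -69.31) and the other two of its group (91.78 and 101.1). On the first it did not lie between them, at -25.3 against -49.98 to -30.69 and against -96.23 and -100.4. Its Spearman correlation across contigs was 0.914 with non-mycorrhizal replicate 3, 0.888 with well-watered mycorrhizal replicate 2 and 0.870 with drought-stressed replicate 3. Contigs are not independent replicates, so no p was attached to these correlations. As a check for a library deposited more than once, the median squared difference of each pair of replicates was set against the value from counting reads alone. The lowest ratio was 7.9, for well-watered mycorrhizal replicates 2 and 3. Libraries from the same plant can exceed counting noise too, so the ratio does not show that replicates are separate plants; each library was counted as 1 sample on its label. Fewer reads lower this ratio, and well-watered mycorrhizal replicate 3 had the fewest; by correlation non-mycorrhizal replicates 1 and 3 were closer (Spearman 0.982 against 0.976).

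**Figure D1:**
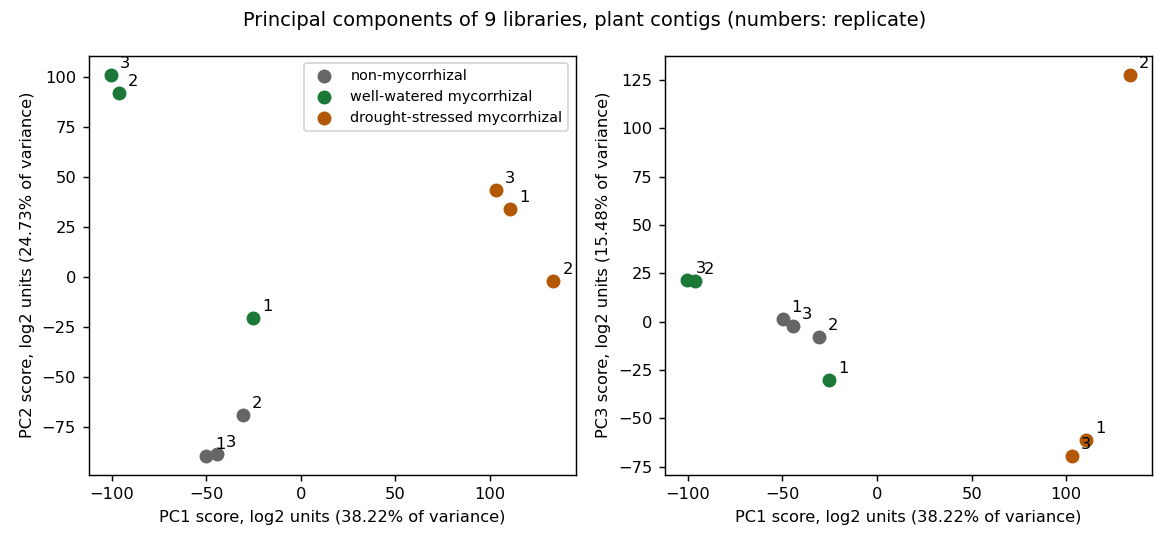
Principal component scores of the 9 libraries (log2 units), with PC1 against PC2 on the left and PC1 against PC3 on the right; each point is a library, coloured by group and numbered by replicate. Drought-stressed libraries lie at the high end of PC1, well-watered mycorrhizal replicate 1 lies nearer to the non-mycorrhizal libraries than to its own group on PC1 and PC2, and drought-stressed replicate 2 stands apart on PC3 at 127.7 against -61.37 and -69.33.

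Well-watered mycorrhizal roots were compared with non-mycorrhizal roots to ask what differs with the symbiosis in the plant without water stress. The labels give months in pots for the non-mycorrhizal plants only and months after inoculation for the mycorrhizal plants only. Growth time and handling at inoculation therefore cannot be told apart from the symbiosis. The term mycorrhiza effect stands here for the difference between these groups. In mycorrhizal roots 411 contigs were higher and 365 lower, which is 3.99% of the 19463 tested (limma, Benjamini-Hochberg adjusted p under 0.05). The median change of these contigs was 1.88 on the log2 scale for those higher and 1.76 for those lower in size, and 190 of the higher and 143 of the lower ones changed at least 4-fold. The higher contigs held 1.55% ± 0.058 of the plant reads of non-mycorrhizal libraries and 5.05% ± 0.75 of those of well-watered mycorrhizal libraries (SD, n = 3). The lower contigs held 5.98% ± 0.41 and 2.45% ± 0.35. These shares are of contigs chosen on the same libraries and are not independent evidence of the change. Contigs whose 3 libraries of one group all lay above or all below the 3 of the other made up 33.3% of those tested, where chance gives 10%.

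The lower contig with the smallest p was k123_67003, with 17250 ± 516 normalised reads in non-mycorrhizal roots and 3436 ± 284 in well-watered mycorrhizal roots (SD, n = 3), a log2 fold change of -2.33 (SE 0.14, limma adjusted p = 0.000296). It lay lower still in drought-stressed roots, at 1275 ± 153. Contig k123_66615 was also lower, by -1.38 (SE 0.12, limma adjusted p = 0.00325), from 8980 ± 185 normalised reads to 3450 ± 128. The higher contig with the smallest p was k123_123367, which went from 766 ± 56 to 3669 ± 419 normalised reads, a log2 fold change of 2.26 (SE 0.17, limma adjusted p = 0.00131). In drought-stressed roots it held 1161 ± 116, a log2 fold change of -1.66 against well-watered mycorrhizal roots (limma adjusted p = 0.000415). Contig k123_110234 had 6, 5 and 5 reads in the non-mycorrhizal libraries and 218, 129 and 50 in the well-watered mycorrhizal ones, a log2 fold change of 5.23 (SE 0.49, limma adjusted p = 0.00355) that did not pass with limma-voom on the reads (adjusted p = 0.0614). With every library thinned to the smallest total the log2 fold change was 4.18 (limma adjusted p = 0.0053). Reads of this contig rose to 825, 424 and 580 in the drought-stressed libraries, a log2 fold change of 1.61 against well-watered mycorrhizal roots (limma adjusted p = 0.0444).

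The number of contigs called for the mycorrhiza effect depended on single libraries. The total of 776 fell to 25, 506 and 11 without non-mycorrhizal replicate 1, 2 or 3 in turn, to 15 and 19 without well-watered mycorrhizal replicate 2 or 3, and to 299 without drought-stressed replicate 1. The drought-stressed libraries enter this comparison only through the common estimate of the spread. It rose to 3365 without well-watered mycorrhizal replicate 1 and to 2219 without drought-stressed replicate 2. It was 328 with limma-voom and 1379 when only the 2 groups compared were fitted.

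Drought-stressed mycorrhizal roots were compared with well-watered mycorrhizal roots for the effect of drought in the symbiosis. Drought left 1650 contigs higher and 2018 lower, 18.9% of those tested (limma, adjusted p under 0.05). The lower contigs changed more in size, with a median log2 fold change of 2.04 against 1.62, and 1038 lower and 595 higher contigs changed at least 4-fold. A change of at least 16-fold was found for 265 lower and 100 higher contigs. The lower contigs held 21.2% ± 4.0 of the plant reads in well-watered mycorrhizal roots and 6.48% ± 0.35 under drought, and the higher ones 8.39% ± 0.93 and 21.3% ± 0.58 (SD, n = 3, contigs chosen on these libraries). In non-mycorrhizal roots the same lower contigs held 19.7% and the same higher contigs 9.97%. Abundant contigs were called more often: 25.5% of the 4866 most abundant contigs and 12.5% of the 4866 least abundant ones passed the test.

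Contig k123_36319 held 1029 ± 35 normalised reads in well-watered mycorrhizal roots and 9443 ± 648 under drought (SD, n = 3), a log2 fold change of 3.19 (SE 0.16, limma adjusted p = 3.27e-05), with 1141 ± 146 in non-mycorrhizal roots. Contig k123_85692 went from 102 ± 28 to 4809 ± 1409, a log2 fold change of 5.55 (SE 0.32, limma adjusted p = 3.71e-05). Among contigs that fell, k123_40873 went from 11610 ± 1942 to 1596 ± 146 normalised reads, a log2 fold change of -2.85 (SE 0.16, limma adjusted p = 3.71e-05), against 12720 ± 1218 in non-mycorrhizal roots. Contig k123_127596 went from 973 ± 69 to 19.9 ± 3.1, a log2 fold change of -5.55 (SE 0.32, limma adjusted p = 3.71e-05), with 17, 36 and 17 reads left in the drought-stressed libraries.

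The total of 3668 contigs for the drought effect was 1676 and 1692 without well-watered mycorrhizal replicate 2 or 3 and 2143 without drought-stressed replicate 1. The higher contigs alone moved to 2544 without well-watered mycorrhizal replicate 1 and to 1041 without non-mycorrhizal replicate 3. With limma-voom 1005 contigs were higher, and with only the 2 groups in the fit 939 were higher and 1276 lower.

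**Figure D2:**
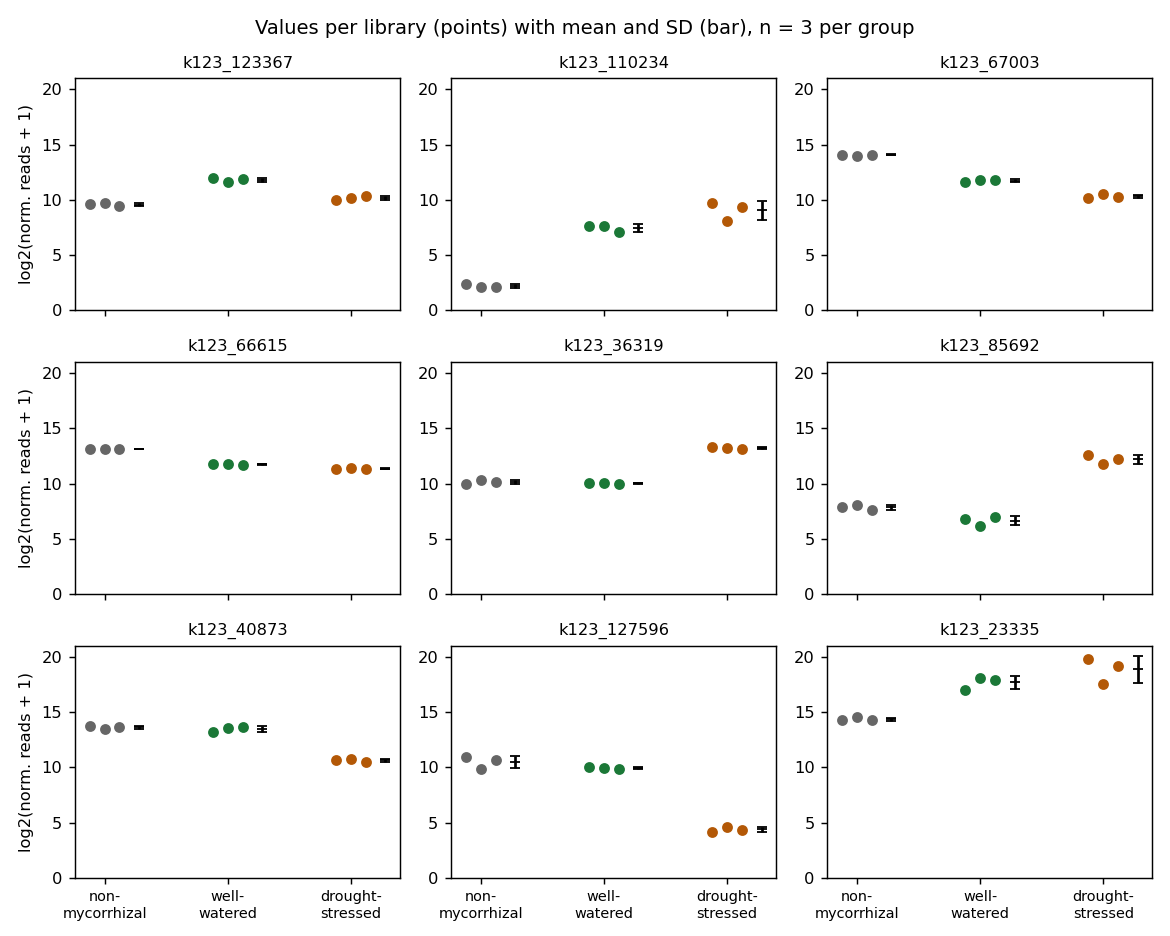
Values of 9 contigs in each library, as log2 of normalised reads plus 1, with points for replicates 1 to 3 from left to right and a bar for the mean and SD of each group (n = 3). The first 4 contigs were named for the mycorrhiza effect and the next 4 for the drought effect; k123_23335, chosen after its values were seen, spreads most in the drought-stressed group (SD 1.20).

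Drought-stressed mycorrhizal roots were also compared with non-mycorrhizal roots, which differ from them in both symbiosis and water supply and may differ in growth time. Here 1657 contigs were higher and 2224 lower, 19.9% of those tested (limma, adjusted p under 0.05), with median log2 changes of 1.51 and 2.07 in size. Without non-mycorrhizal replicate 1 the counts were 910 and 1286, and without non-mycorrhizal replicate 3 they were 731 and 1114. The higher contigs alone numbered 955 and 1006 without drought-stressed replicate 1 or 3.

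**Figure D3:**
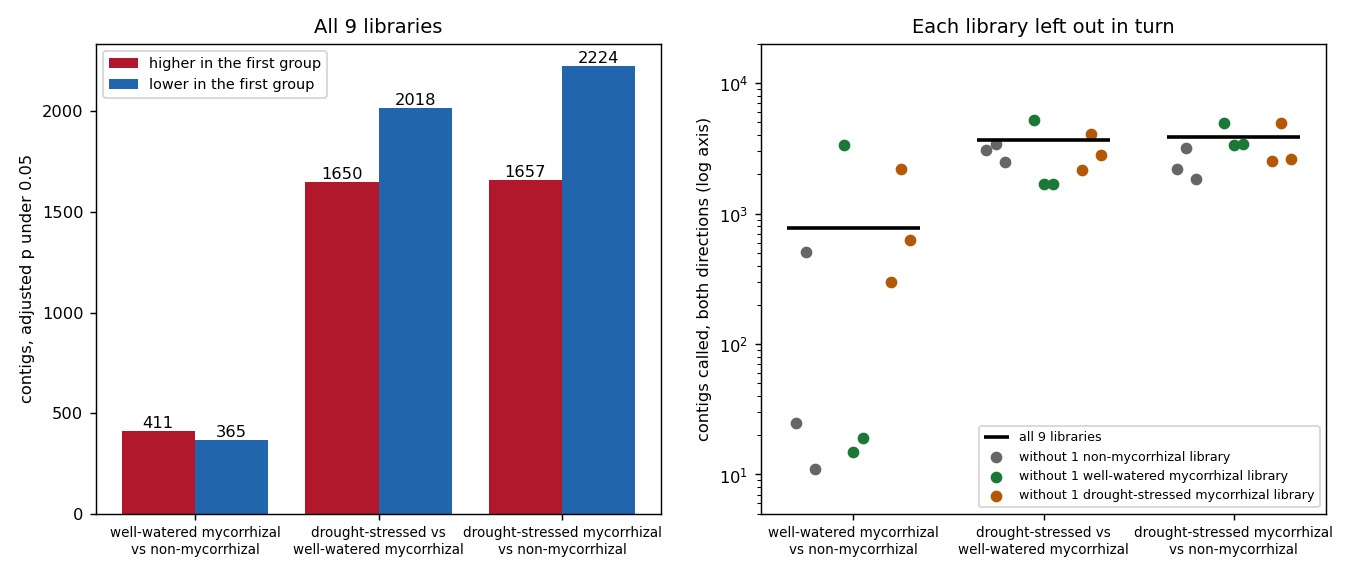
Contigs with an adjusted p under 0.05 in the 3 comparisons. Left, bars give contigs higher (411, 1650 and 1657) and lower (365, 2018 and 2224) with all 9 libraries; right, on a log axis, lines give the totals with all libraries and points the totals with 1 library left out, from 11 to 3365 for the mycorrhiza effect and from 1676 to 5217 for the drought effect.

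Over the 3 groups, 5644 contigs (29.0% of those tested) were called in at least 1 comparison. The largest class of called contigs, with 1185, was lower under drought than in both other groups and was not called between those 2 groups, with a median log2 fold change of -2.17 against well-watered mycorrhizal roots. A further 780 contigs were higher under drought than in both, by a median of 1.65. Many contigs were called in a single comparison. Against non-mycorrhizal roots alone, 813 were lower and 692 higher in drought-stressed roots. Against well-watered mycorrhizal roots alone, 645 were lower and 753 higher under drought. A total of 153 contigs were higher in both mycorrhizal groups than in non-mycorrhizal roots and were not called between the mycorrhizal groups, and 159 were lower in both. Another 121 contigs were higher in well-watered mycorrhizal roots than in either other group, with drought-stressed and non-mycorrhizal roots not called apart, and 85 were lower in the same manner. For 19 contigs the level was higher with mycorrhiza and higher again under drought, and for 46 it was lower at both steps. These numbers rest on the calls above and move with the same libraries.

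Of the 411 contigs higher with mycorrhiza, 142 fell under drought, 19 rose and 250 were not called. Of the 365 lower with mycorrhiza, 98 rose under drought, 46 fell and 221 were not called. Contigs called in both comparisons thus went opposite ways in 240 cases and the same way in 65, against 73.6 and 72.7 for independent lists of these lengths. Simulated data with no effect gave a median of 0 calls in each comparison and so an overlap of 0, which cannot show what the shared libraries add. Both comparisons use the well-watered mycorrhizal libraries, with opposite signs, and 3 libraries cannot be split into parts of at least 2, so part of the excess of opposite calls may come from the shared libraries. Across contigs the fold changes correlated at r = -0.419, and simulated groups with no effect gave a mean of -0.450 (SD 0.341, 100 draws). The covariance was -0.631 against -0.204 in the simulation (SD 0.163), a difference of -0.426. The opposite calls numbered 3 without non-mycorrhizal replicate 3, 12 without replicate 1 and 138 without replicate 2 of that group. They numbered 6 and 8 without well-watered mycorrhizal replicate 2 or 3 and 77 without drought-stressed replicate 1, and they rose to 1690 without well-watered mycorrhizal replicate 1 and 524 without drought-stressed replicate 2.

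**Figure D4:**
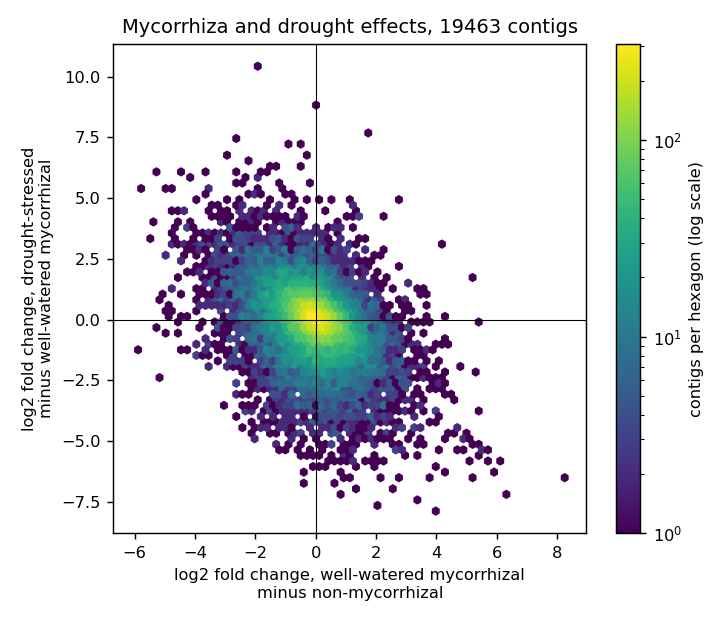
Log2 fold change of the mycorrhiza effect (x axis) against that of the drought effect (y axis) for 19463 contigs, shaded by the number of contigs per hexagon on a log scale. The cloud slopes downwards, with r = -0.419, and the shared well-watered mycorrhizal libraries alone give a mean of -0.450 in simulation.

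No contig had at least 10 reads in each of the 6 mycorrhizal libraries and 0 in all 3 non-mycorrhizal ones, and none showed the reverse. The rule that kept contigs as plant was not given, so contigs read only in mycorrhizal roots may have been removed beforehand. Contigs at 0 in all 3 non-mycorrhizal libraries numbered 13, and they held at most 0.00235% of the plant reads of any mycorrhizal library. Contigs at 0 in all 3 libraries numbered 4 in the well-watered mycorrhizal group and 81 in the drought-stressed group. Well-watered mycorrhizal replicate 1 had 60 contigs at 0, against 326 and 448 in replicates 2 and 3. That library therefore limits any count of contigs at 0 in all 3 libraries of its group. With at least 10 reads in each well-watered mycorrhizal library, 13 contigs had 0 reads in all drought-stressed libraries, and 1 contig showed the reverse.

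The 10 most abundant contigs held 3.36% ± 0.16 of the plant reads in non-mycorrhizal roots, 4.10% ± 0.29 in well-watered mycorrhizal roots and 7.11% ± 2.38 in drought-stressed roots (SD, n = 3). Each pair of groups gave an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 allow. The 100 most abundant contigs held 14.6% ± 0.18, 14.9% ± 0.47 and 17.7% ± 2.1, with an exact permutation p of 0.4 between non-mycorrhizal and well-watered mycorrhizal roots and 0.1 for both other pairs. The single most abundant contig of each library held 0.503% ± 0.073, 1.15% ± 0.37 and 3.01% ± 1.90, with an exact permutation p of 0.3 between the mycorrhizal groups and 0.1 for both other pairs. The contig with most reads under drought, k123_23335, was singled out after its values were seen. It was the single most abundant contig in every mycorrhizal library, so the shares above include it and are not separate from it. It took 4.78%, 0.996% and 3.26% of the plant reads in drought-stressed replicates 1 to 3, where the 10 most abundant contigs together held 9.24%, 4.54% and 7.55%. Its log2 fold change was 3.33 in well-watered mycorrhizal against non-mycorrhizal roots (SE 0.50, limma adjusted p = 0.0147) and 4.49 in drought-stressed against non-mycorrhizal roots (SE 0.50, limma adjusted p = 0.000379). Between the mycorrhizal groups it was 1.17 (SE 0.50, limma adjusted p = 0.13), and it moved both ways with single libraries. It was 1.84 without drought-stressed replicate 2 (limma adjusted p = 0.00529), 0.67 without drought-stressed replicate 1 (limma adjusted p = 0.372), 1.00 without drought-stressed replicate 3 (limma adjusted p = 0.271) and 0.82 without well-watered mycorrhizal replicate 1 (limma adjusted p = 0.279). The mycorrhiza call of this contig did not pass without non-mycorrhizal replicate 1 or 3 (limma adjusted p = 0.0573 and 0.0891) or without well-watered mycorrhizal replicate 2 or 3 (limma adjusted p = 0.0813 and 0.0881).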

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

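Alternatives other than those said to be added were chosen before the data were examined. The 9 named contigs were each refitted in 15 settings: the replicate block, the compared groups alone, thinning, limma-voom, other scalings and each library left out. All kept their sign, as did the correlation, and other contigs were not followed one by one. Contigs named by rule were chosen for no overlap between the groups, so leaving out 1 library could not reverse them. The replicate block and the fits of the compared groups alone leave fold changes and the correlation unchanged by design. The kept signs in these settings are therefore no evidence of stability. Leaving out each library in turn gave 6 to 1588 contigs higher and 4 to 1777 lower for the mycorrhiza effect, 716 to 2544 and 945 to 2673 for the drought effect, and 731 to 2211 and 1114 to 2767 for the combined effect. Opposite calls of the mycorrhiza and drought effects ranged from 3 to 1690 and same-direction calls from 2 to 217, and the correlation from -0.596 to -0.341. With limma-voom the mycorrhiza effect had 169 higher and 159 lower contigs, the drought effect 1005 higher, and the overlap 102 opposite and 39 same. With only the compared groups in the fit the mycorrhiza effect had 775 and 604, and the drought effect 939 and 1276. The replicate block gave 234 and 181 for the mycorrhiza effect and 123 opposite and 40 same calls, with 3130 drought and 3278 combined calls in all. No pairing by replicate number was seen: correlations of the deviations of same-numbered libraries ran from -0.065 to 0.018, 0 of 9 pairs were over 0.1, and 1 library correlated best with its own number. With 3 libraries per group, this cannot show that the samples share no pairing.

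Further settings were added after seeing the data. Without both well-watered mycorrhizal replicate 1 and drought-stressed replicate 2, calls were 3121 and 3279 for mycorrhiza, 3470 and 3672 for drought and 3361 and 3958 combined, with 2934 opposite and 452 same. Weights per library without robust moderation gave 5363 and 5990, 4528 and 4727, and 5700 and 6204, with 4841 opposite and 1193 same; this estimate put a weight of 817.5 on non-mycorrhizal replicate 3 against 0.1028 to 1.337 on the others, gave a convergence warning and is not used. The cause of these shifts was not tested. In all, 72 counts of calls or of shared calls moved by over 1.5 times. The 182 values that did not move also include values judged by other rules. These are the correlation (within the simulated SD of 0.341), contigs read in one group only and shares of the most abundant contigs. The 182 is therefore no measure of how stable the counts of calls were. Other filters, thinning to the smallest total, other pseudocounts and other scalings kept each call count within 1.5 times. Of the 8 contigs named by rule, 1 lost its call in 1 setting. DESeq2 and edgeR settings were left out because the deposited unit is log2, although the recovered reads would allow them, and those reads were tested with limma-voom only. Set tests on gene lists were not run, as the contigs carry no gene names. Thinning every library to the smallest total, 7454712 plant reads, left 18775 contigs past the filter and gave 754, 3492 and 3763 calls for the mycorrhiza, drought and combined effects.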

Other observations

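The tests of splits were chosen after the counts had been seen, as were the comparisons with other libraries and with held-out libraries below; the other tests were set before their values were seen, on positions of libraries and an order of rows that had been noticed in the data.

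In 2-group fits, the real split of 6 libraries called 1379 contigs for the mycorrhiza effect, 2215 for the drought effect and 3945 for the combined effect, and the highest of the other splits called 0 in each (limma). At an unadjusted p under 0.05 the real splits gave 5495, 5687 and 6876 contigs and the highest of the others 2464, 2210 and 1770. In each comparison 1 of the 10 splits, the real one, gave as many calls. Because 10 splits cannot give a share under 0.05, the splits do not settle whether chance made the counts.

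Non-mycorrhizal replicate 3 lay between replicates 1 and 2 of its group. In 829 contigs read in both of those libraries and at least 4-fold apart, a linear mixture with a weight of 0.325 for replicate 2 left a residual of 0.23 (log2). Interpolation on the log scale left 0.657, 2.859 times as much. This argues only against an intermediate state that is graded on the log scale. A plant with intermediate transcript amounts on the linear scale would fit like a mixture. The weight of replicate 2 was 0.306 from contigs higher in replicate 2 and 0.355 from contigs higher in replicate 1. The difference of -0.05 (interval -0.067 to -0.033) was within the tolerance of 0.1 set beforehand. The same fit in 5 other libraries with at least 100 such contigs left residuals of 0.421 to 0.729. Their best weights for the second library of the pair were 1.0, 1.0, 0.98, 0.925 and 0.02, at or near a single library. Those residuals mostly reflect the distance to the nearest group mate and are no benchmark for a mixture. A candidate explanation for the position of non-mycorrhizal replicate 3 is that material or reads of replicates 1 and 2 were mixed in it. Roots made of the same tissues in intermediate proportions would also add linearly, and no test here separates these explanations. If replicate 3 is not independent, the spread among non-mycorrhizal libraries is understated, and without it the mycorrhiza effect had 11 calls, the drought effect 2503 and the combined effect 1845.

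Well-watered mycorrhizal replicate 1 lay toward the non-mycorrhizal libraries on the second principal component (-20.6 against -89.49 to -69.31, and 91.78 and 101.1 in its group) but was not between them on the first. In 330 contigs at least 4-fold higher in replicates 2 and 3 than in every non-mycorrhizal library, its median excess over the non-mycorrhizal mean was 1.232 (interval over contigs 1.061 to 1.424, log2), against 3.06 in replicates 2 and 3 and at most 0.131 in single non-mycorrhizal libraries, and 79.1% of these contigs were higher in it than in every non-mycorrhizal library. With each non-mycorrhizal library held out of the choice of contigs, that library reached 0.015 to 0.384 and replicate 1 reached 1.105 to 1.271. In these contigs replicate 1 thus lay further toward replicates 2 and 3 than the non-mycorrhizal libraries did. On the 330 contigs drought-stressed replicates 1 to 3, also labelled mycorrhizal, reached only 0.646, 0.392 and 0.86. The excess therefore does not sort libraries by symbiosis. A non-mycorrhizal plant under a wrong label is not excluded, and the test set beforehand left this open. The interval leaves out the spread between plants, which rests on 3 libraries. In the lower contigs held-out non-mycorrhizal replicate 2 reached -0.725 where well-watered mycorrhizal replicate 1 reached -1.018. In 459 lower contigs the median change was -0.711 in replicate 1, -3.593 in replicates 2 and 3, and -0.993, -0.851 and -1.074 in the drought-stressed libraries. Libraries labelled mycorrhizal can thus lie far from the profile of replicates 2 and 3, so a low share of it is no sign of less mycorrhiza. The share of this profile in replicate 1 came to 0.156 from the higher and 0.44 from the lower contigs, a difference of -0.284. The same estimator gave differences of -0.154, -0.42 and -0.024 in held-out non-mycorrhizal replicates 1, 2 and 3. On the same contigs it gave -0.349, -0.412 and -0.317 in well-watered mycorrhizal replicate 1. Since the estimator missed by more than the tolerance of 0.1 in non-mycorrhizal replicates 1 and 2, which hold no mycorrhizal share, it decides nothing here. Both admixture and a smaller colonised share of the root, the latter a biological explanation, may still apply.

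The first 2271 rows of the tables precede a part sorted by contig identifier. Of these contigs 98.9% were called in at least 1 comparison here, against 19.5% of the sorted part. In 14 of 15 windows of 150 rows the order followed the fold change of 1 of the 3 comparisons with a Spearman rho below -0.75, and in 0 of 116 windows of the sorted part. The block may be the set of contigs that the submitters had called changed.

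Well-watered mycorrhizal replicates 2 and 3, whose labels carry the same sequencing sample index, had 1 contig at least 4-fold apart among 10641 compared and a median squared difference 7.9 times sampling noise; their Spearman correlation of 0.976 was below the 0.982 of non-mycorrhizal replicates 1 and 3. Drought-stressed replicate 2 stood at 127.7 on the third principal component against -61.37 and -69.33 for the other two of its group.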
